A study of Mus musculus with 10 samples.

How the data were processed

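Total RNA of mouse hippocampus was extracted with a silica column kit and made into libraries with a stranded total RNA kit, per the labels' protocols. The authors deposited estimated counts per Ensembl gene in a single table of 28871 genes and 10 samples, obtained with Salmon for the mouse genome build mm10 after FastQC, per the submitters' processing notes. Their versions, the annotation release and the way in which transcript estimates were summed per gene are not given in the sources used here. The deposited counts are whole numbers, so that rounding them changed nothing, and the largest values carry 6 significant digits. Genes with a total of less than 2 over the 10 samples are absent from the table. Salmon assigns reads that fit several transcripts by estimation, so that near-identical genes, such as the copies of the 7SL RNA gene or members of the H2 and hemoglobin families, share reads and their single values are less certain. The kit is made for total RNA and does not select poly(A) RNA, so that noncoding, nuclear and mitochondrial RNAs are part of the totals.

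Groups were taken from the treatment label: 5 Visudyne samples (3, 6, 9, 12 and 15) and 5 vehicle samples (1, 4, 7, 10 and 13). The labels describe the samples as hippocampus of mice but do not state that each sample is a single animal. The p-values therefore measure the spread between these samples. No batch, date or processing order is given. Counts of all 45 pairs of libraries differed by far more than sampling noise (chi-square per degree of freedom 10.5 to 74.1 over 17150 genes). No column therefore repeats the sequencing of another library. Separate libraries of the same animal could also differ in this way, so separate animals are not shown. Each library was counted as a sample of its own. Gene symbols and coordinates came from the GENCODE annotation for the same assembly: 28564 identifiers matched, and 307 without a symbol held 0.134% of the counts.

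The main test was edgeR's quasi-likelihood F-test (edgeR 4.0.16, R 4.3.3) on the deposited counts, with edgeR's default filter on low counts, which left 19093 genes, TMM normalization, no covariate and Benjamini-Hochberg adjustment with a threshold of 0.05. CPM values were computed with the TMM-scaled totals. The common dispersion was 0.0214, a biological coefficient of variation of 14.6%. SEs of log2 fold changes were derived from the F statistics. The 41 gene lists, of cell types, brain regions and pathways, were written before the data were examined and tested with limma's camera (limma 3.58.1) on log2 CPM with a prior count of 2, the preset correlation of 0.01 and at least 5 tested members. Beside it stand camera with an estimated correlation, fry, and an exact two-sided permutation test of each list's mean log2 CPM per sample over all 252 assignments of 5 and 5 samples, whose smallest p is 0.0079. Exact p-values of library measures come from the same two-sided test.

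The genes named in the report were fixed by a rule before the data were examined. It takes all genes past the threshold, up to 15 per direction, and fills each direction to 10 by smallest p among annotated genes of a mean log2 CPM of at least 1. It adds the 3 members of smallest p of each list that passed or whose median was among the 4 highest or lowest, and 15 genes named whatever their values. Other members are given as examples of a list and were chosen after their values were seen.

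The procedure was tested on simulated data for the Visudyne against vehicle comparison, with 19093 genes of which 200 outside the lists were changed by known folds. The 24 tested members of the fibroblast list were raised 1.25-fold as well. Of the 200 genes, the procedure called 26% of those changed 1.25-fold, 36% at 1.5-fold, 66% at 2-fold and 92% at 3-fold. Of all 114 calls 3.51% were false, with the raised list members counted as changed. The list test called the 1 list that had been shifted. Simulated genes varied independently of each other, while members of real lists varied together. These shares and the list result may therefore not hold for the real samples. Precision differs with abundance: Mbp had at least 20019 counts per sample and Col1a1 at least 343, while H2-Eb1, H2-Ab1, Foxc2 and Timp1 rest on low counts, down to 8 per sample for Timp1.

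Alternatives covered other normalizations (relative log expression and upper-quartile factors), no filter or a stricter filter on low counts, removal of mitochondrial genes, DESeq2 1.42.0, limma voom with and without sample quality weights, a minimum fold change of 1.2, the sample number or 1 surrogate variable (sva 3.50.0) as covariate, and leaving out each sample in turn. The omission of the 2 samples at the ends of the first principal component was added after the data were examined. No column of the table was left out.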

Results

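The series profiled the whole hippocampus of male C57BL/6J mice, 2 months old, after damage to the lymphatic vessels of the meninges. Visudyne, a formulation of the photosensitizer verteporfin, was delivered into the cisterna magna and activated through the intact skull with red light of 689 nm. Control animals received vehicle and the same light. The treatment was given again after 2 weeks, and the hippocampus was collected 2 weeks after the last procedure. The comparison asks whether impaired meningeal lymphatic drainage was accompanied by altered hippocampal gene expression. Total RNA of 5 Visudyne and 5 vehicle samples was sequenced. Sequencing depth ranged from 51165271 to 68895223 estimated counts per sample, and did not differ between the groups by the exact permutation test (p = 0.516, n = 5 each). Values below are CPM, counts scaled to a common library total, as mean ± SD with n = 5 per group, and log2 fold changes are Visudyne minus vehicle with their SE.

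Hippocampi of Visudyne-treated mice contained more mRNA of 3 collagen genes and of a sulfate transporter. Col12a1, which encodes a fibril-associated collagen, rose from 10.1 ± 0.762 to 17.2 ± 1.75 CPM (log2 fold change 0.77, SE 0.08, edgeR adjusted p = 0.0084). Col1a1, the main chain of type I collagen, rose from 8.42 ± 2.30 to 19.04 ± 2.47 CPM (1.18, SE 0.16, edgeR adjusted p = 0.0485). Col6a2, a chain of the microfibrillar type VI collagen, rose from 5.20 ± 0.767 to 9.38 ± 1.23 CPM (0.85, SE 0.12, edgeR adjusted p = 0.0485). Slc26a2, a sulfate transporter needed for the sulfation of matrix proteoglycans, rose from 12.3 ± 0.800 to 16.9 ± 0.551 CPM (0.45, SE 0.05, edgeR adjusted p = 0.0227). In each of these 4 genes all 5 Visudyne samples lay above all 5 vehicle samples. They are protein-coding genes on separate chromosomes (mm10): Col12a1 (ENSMUSG00000032332) spans positions 79598991 to 79718831 of chromosome 9 on the minus strand, and Slc26a2 (ENSMUSG00000034320) positions 61192919 to 61211612 of chromosome 18 on the minus strand. Col6a2 (ENSMUSG00000020241) spans 76595762 to 76623630 of chromosome 10 on the minus strand, and Col1a1 (ENSMUSG00000001506) 94936224 to 94953042 of chromosome 11 on the plus strand.

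**Figure D1:**
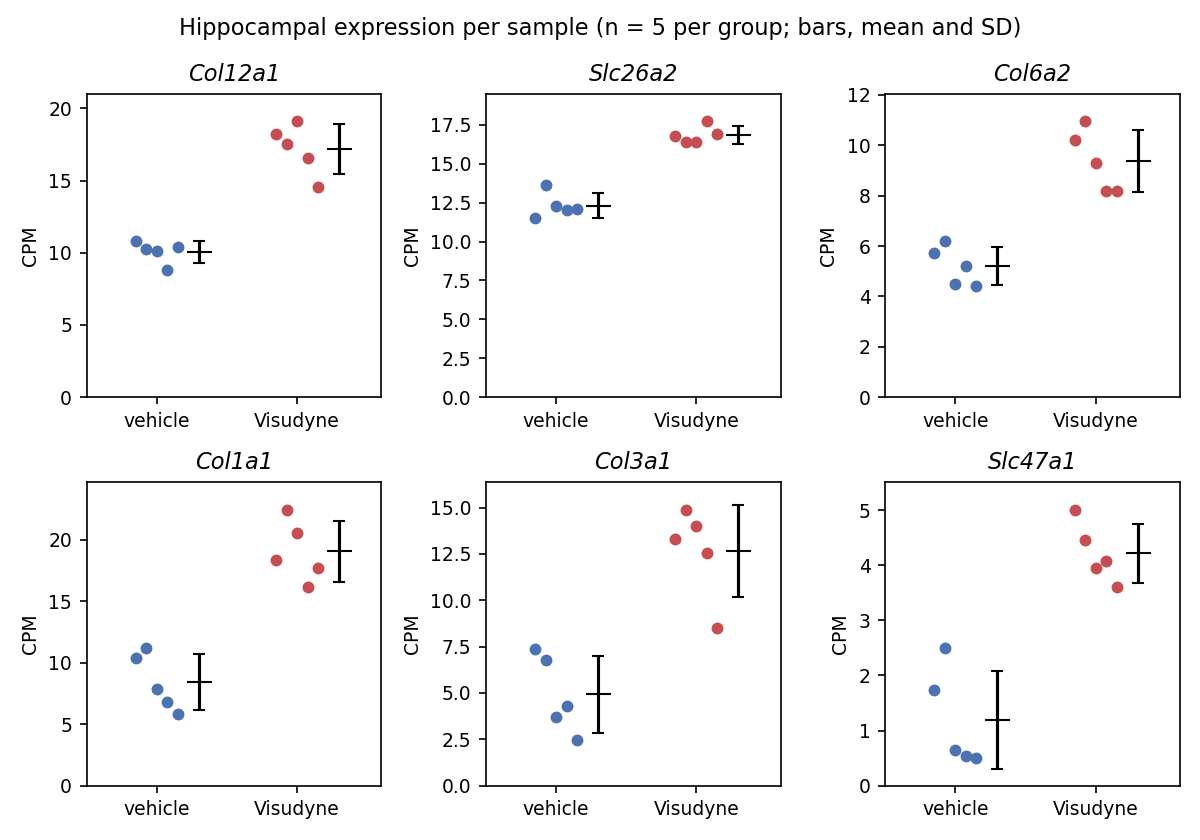
CPM (vertical axis, from 0) of the 4 genes past the threshold and of Col3a1 and Slc47a1, which did not pass, in each vehicle (blue) and Visudyne (red) sample, with the group mean and SD in black. In all 6 genes the 5 Visudyne samples lie above the 5 vehicle samples, for example 14.6 to 19.1 against 8.78 to 10.8 CPM for Col12a1.

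Of 19093 genes tested with edgeR's quasi-likelihood test, 4 were higher and 0 lower with Visudyne at an adjusted p under 0.05. At an unadjusted p under 0.05 there were 218 higher and 107 lower genes, against 955 expected by chance in both directions. DESeq2 called 16 higher and 2 lower genes, and limma voom called 4 and 0. All 5 Visudyne samples lay above all vehicle samples in 61 genes and below them in 22, where chance alone gives 0.397% of genes, or 76, in each direction. The count of higher genes fell to 0 when Visudyne 3, Visudyne 6 or vehicle 7 was left out, and to 1, Col12a1, when Visudyne 9, Visudyne 12, Visudyne 15, vehicle 10 or vehicle 13 was left out. It was 0 when a fold change above 1.2 was required. The log2 fold changes themselves stayed similar over the 22 alternatives: 0.73 to 0.86 for Col12a1, 0.42 to 0.49 for Slc26a2, 0.79 to 0.94 for Col6a2 and 1.08 to 1.31 for Col1a1. All alternatives refit the same samples or most of them, so this similarity is no independent support for the differences.

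Among annotated genes of a mean log2 CPM of at least 1, the 6 next by p that were higher did not pass the test; 4 of them encode secreted or matrix proteins and 2 encode transporters. Adamtsl3, a secreted ADAMTS-like glycoprotein, measured 2.45 ± 0.711 CPM in vehicle and 5.40 ± 0.683 CPM in Visudyne samples (log2 fold change 1.14, edgeR adjusted p = 0.103). Col3a1, the fibrillar type III collagen, measured 4.92 ± 2.10 and 12.6 ± 2.47 CPM (1.36, edgeR adjusted p = 0.430). The organic cation exporter Slc47a1 measured 1.19 ± 0.892 and 4.22 ± 0.537 CPM (1.83), fibronectin (Fn1) 20.4 ± 3.94 and 31.7 ± 4.98 CPM (0.64), and the matrix Gla protein gene Mgp 6.42 ± 2.14 and 12.2 ± 1.80 CPM (0.92), each with an edgeR adjusted p of 0.720. Slc12a7, a potassium-chloride cotransporter, measured 3.14 ± 0.217 and 4.19 ± 0.328 CPM (0.42, edgeR adjusted p = 0.764). All 5 Visudyne samples exceeded all vehicle samples in these genes except Fn1, where 4 did. With the sample number as a covariate all of them except Slc12a7 passed (Slc47a1 with an adjusted p of 0.032), and with voom and sample quality weights Adamtsl3, Col3a1, Slc47a1 and Mgp did.

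The 10 highest-ranked genes with negative fold changes, again among annotated genes of a mean log2 CPM of at least 1, each had an edgeR adjusted p of 0.9999. Among them were the ribonucleoprotein gene Hnrnpul1 (45.5 ± 4.42 CPM in vehicle and 36.3 ± 4.62 in Visudyne, log2 fold change -0.33), Fbrs (-0.50), Rtl3 (-0.38), the protocadherin Pcdhb14 (-0.21), Ly6e (-0.50), Zfp995 (-0.38), the polo-like kinase Plk5 (-0.28), Tmem144 (-0.17) and the metalloprotease Adamts1 (-0.14). For the cadherin gene Fat3 the log2 fold change of -4.81 came mostly from vehicle 7, which measured 45.3 CPM while the next vehicle sample measured 1.88 CPM.

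The 24 markers of meningeal and perivascular fibroblasts, the connective tissue cells of the brain's coverings and vessel walls, stood highest among 41 gene lists fixed in advance. Their median log2 fold change was 0.29, 23 of 24 were positive, and the list passed a competitive test with the preset correlation (limma camera adjusted p = 5.9e-16). It did not pass with an estimated correlation (adjusted p = 0.482), since its members varied together between samples (correlation 0.698). Over all genes 1 member passed (Col1a1), and 7 passed when adjusted over the list alone: Col1a1, Col3a1, Slc47a1, Mgp, Col1a2 (0.78), Bgn (0.52) and Islr (0.38). With the sample number as a covariate the first 6 of these passed over all genes. Of the others, Foxd1 (0.65, SE 0.28), Osr1 (0.47, SE 0.20) and Foxc1 (0.30, SE 0.15) were higher by about 2 SE, and 5 examples differed by less than their SE: Slc6a13 (0.18, SE 0.32), Slc22a6 (0.15, SE 0.34), Dcn (0.18, SE 0.29), Ptgds (0.16, SE 0.30) and Lum (0.04, SE 0.19). The list score, the mean log2 CPM of its members, was 2.80 ± 0.504 in vehicle and 3.33 ± 0.216 in Visudyne samples (exact permutation p = 0.0952, n = 5 each). Vehicle 1 (3.33) and vehicle 4 (3.29) lay within the Visudyne range, and vehicle 7 (2.53), vehicle 10 (2.70) and vehicle 13 (2.16) below it. The median was 0.46 without vehicle 1, 0.44 without vehicle 4 and 0.17 without vehicle 13, and the call was kept in each case.

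Genes of immune cells that live at the brain's borders and of antigen presentation were higher as lists with the preset correlation. In the list of border macrophages, monocytes and neutrophils (10 members tested, median 0.28, camera adjusted p = 0.0013; adjusted p = 0.482 with an estimated correlation) 9 members were positive and 1 passed when adjusted over the list alone. This was Cd74, the invariant chain of class II molecules, at 1.55 ± 1.08 CPM in vehicle and 4.08 ± 0.743 CPM in Visudyne samples (log2 fold change 1.39). Ccr2, a monocyte chemokine receptor, had 0.60 (SE 0.22), and Ms4a7, a macrophage gene, 0.41 (SE 0.27). Other macrophage markers differed by about their SE or less: Mrc1 0.16 (SE 0.23), Cd163 0.15 (SE 0.18), Lyve1 0.23 (SE 0.24) and Cbr2 0.12 (SE 0.26). Pf4 was negative (-0.42, SE 0.41). Of the 19 listed members 9 were not tested, among them the neutrophil genes S100a8, S100a9, Retnlg, Ngp and Camp. The result therefore does not cover neutrophils. Of 22 antigen presentation genes (median 0.07, camera adjusted p = 0.0011; adjusted p = 0.922 with an estimated correlation) 15 were positive and 2 passed when adjusted over the list alone, Cd74 and the class II gene H2-Eb1 (a 2.29-fold difference). H2-Ab1 (1.24, SE 0.42) and H2-Aa (1.09, SE 0.52), also class II, did not, and the class I genes H2-K1 (0.08), H2-D1 (0.09) and B2m (0.02) were close to 0. In the main test no member of these lists passed over all genes. Cd74 passed with the sample number as a covariate and with voom and sample quality weights, and H2-Eb1 with the sample number. The macrophage list lost its call without vehicle 13 (median 0.17, camera adjusted p = 0.0566) and kept it without Visudyne 3 (median 0.17). The antigen presentation list lost it without vehicle 10 (median 0.04, camera adjusted p = 0.0973) and kept it with medians of 0.10 without vehicle 1, 0.11 without vehicle 4 and 0.04 without vehicle 13.

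The 14 lymphatic endothelium genes tested had a median log2 fold change of 0.13, with 11 positive (camera adjusted p = 0.0345; adjusted p = 0.482 with an estimated correlation). Their score was 2.49 ± 0.120 in vehicle and 2.75 ± 0.0540 in Visudyne samples, and all 5 Visudyne samples lay above all vehicle samples (exact permutation p = 0.0079, the smallest this design allows, and 0.325 after adjustment over the 41 lists). The forkhead factor Foxc2, which acts in lymphatic valves and in meningeal fibroblasts, passed when adjusted over the list alone, at 0.469 ± 0.257 and 1.26 ± 0.339 CPM (log2 fold change 1.43). Pdpn (0.22, SE 0.11), Stab1 (0.21, SE 0.12), Lyve1 (0.23, SE 0.24), Flt4 (0.03, SE 0.12) and Prox1 (-0.09, SE 0.07) did not. Some members also stand in other lists: Prox1 among dentate granule cell markers, Reln among interneuron markers and Lyve1 among border macrophage genes. The score therefore does not measure lymphatic vessels alone. The call was lost without Visudyne 3 (median 0.07, camera adjusted p = 0.0693), without vehicle 13 (0.08, 0.273), without vehicle 1 and Visudyne 15 together (0.09, 0.0551), with no filter on low counts (0.05, 0.245) and with a filter of 1 CPM in 5 samples (0.05, 0.440).

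Reactive astrocyte genes (28 tested, 20 positive, median 0.08) had a camera adjusted p of 0.0210, and an adjusted p of 0.954 with an estimated correlation. Inflammatory cytokine and complement genes (21 tested, 14 positive, median 0.08) had 0.04996, and an adjusted p of 0.922 with an estimated correlation. No member of either list passed when adjusted over the list alone. Their members of smallest p were Timp1, a metalloprotease inhibitor (0.85, SE 0.33), the oncostatin M receptor Osmr (0.18, SE 0.08), the complement genes C4b (0.20, SE 0.08) and C2 (0.38, SE 0.22), and the complement inhibitor Serping1 (0.34, SE 0.18). The astrocyte call was lost without Visudyne 3 (camera adjusted p = 0.0693), Visudyne 12 (0.144) or vehicle 13 (0.488, median 0.01), and kept with medians of 0.15 without vehicle 1 and 0.05 without vehicle 7. The cytokine call was lost without Visudyne 3 (0.0693), Visudyne 9 (0.230, median 0.06), vehicle 10 (0.197) or vehicle 13 (0.331), and with no filter on low counts (0.332), and kept without vehicle 1 (median 0.16).

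Markers of dentate granule cells, the principal neurons of the dentate gyrus, were lower as a list with the preset correlation. Of 17 markers 16 were negative, with a median log2 fold change of -0.09 (camera adjusted p = 1.7e-06; adjusted p = 0.482 with an estimated correlation). The lactase gene Lct measured 56.0 ± 4.87 CPM in vehicle and 49.3 ± 3.57 in Visudyne samples (-0.18), and Stxbp6, a syntaxin-binding protein gene, 90.4 ± 4.75 and 80.6 ± 7.39 CPM (-0.17). Plk5 measured 17.2 ± 2.33 and 14.2 ± 1.30 CPM. Prox1 (-0.09, SE 0.07) and Calb1 (-0.04, SE 0.08), 2 widely used granule cell markers, differed by little more than their SE or less. No member passed when adjusted over the list alone, and the scores, 5.46 ± 0.0866 and 5.37 ± 0.116, overlapped (exact permutation p = 0.214). The median was -0.06 without vehicle 10, and the call was kept.

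All 13 protein-coding genes of the mitochondrial genome had negative fold changes, with a median of -0.07 (camera adjusted p = 0.0210; adjusted p = 0.973 with an estimated correlation). The largest were mt-Atp8 (392 ± 47.4 and 353 ± 13.8 CPM, -0.15), mt-Co1 (-0.15) and mt-Nd1 (-0.12), and no member passed when adjusted over the list alone. The call was lost without Visudyne 12 (median -0.04, camera adjusted p = 0.180), Visudyne 15 (-0.06, 0.0799), vehicle 4 (-0.03, 0.261) or vehicle 7 (-0.02, 0.649), without vehicle 1 and Visudyne 15 together (-0.09, 0.0731), and with the sample number as a covariate (-0.06, 0.0825). Mitochondrial ribosomal RNA took 20.3 ± 1.21% of the counts in vehicle and 18.8 ± 0.955% in Visudyne samples (exact permutation p = 0.0794, n = 5 each, adjusted 0.794 over 10 library measures). None of the 41 lists passed with the estimated correlation, with limma's rotation test fry (lowest adjusted p = 0.780) or with the exact test of scores after adjustment (lowest 0.325).

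**Figure D2:**
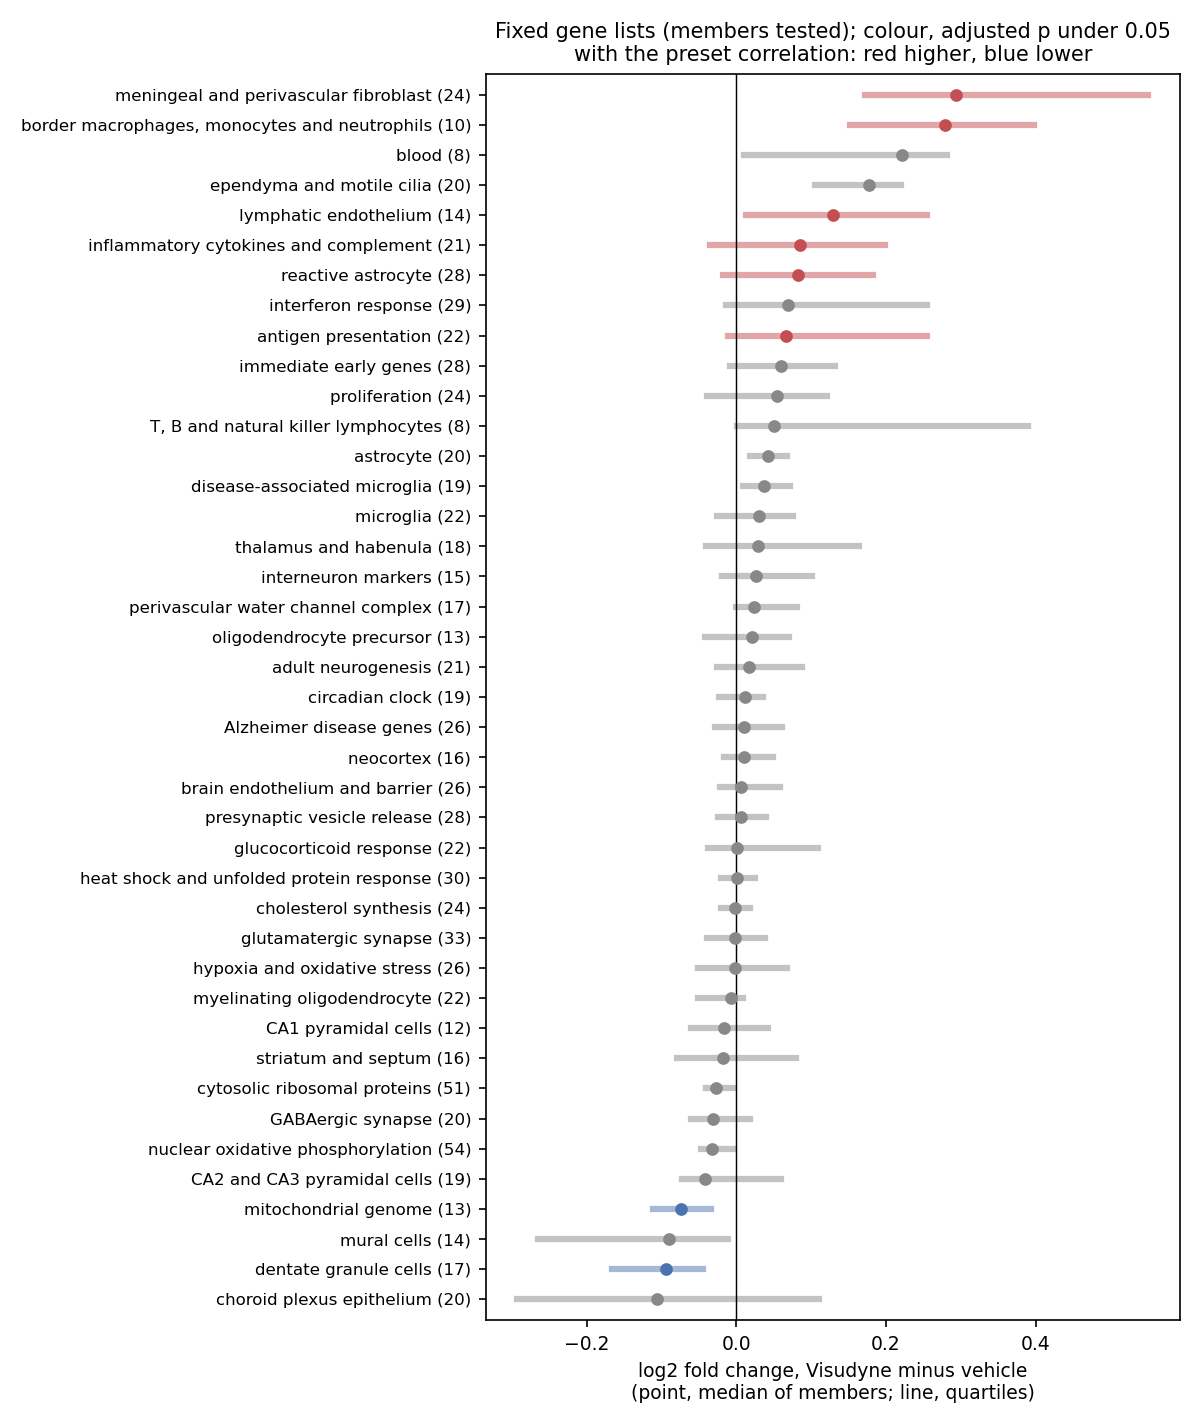
Median log2 fold change (horizontal axis, Visudyne minus vehicle) of the tested members of each of the 41 gene lists, with the quartiles of the members as a line and the number of members in parentheses. Red lists (6) were higher and blue lists (2) lower with the preset correlation, and fibroblast markers have the highest median, 0.29.

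Apart from the dentate granule cell list, neuronal and synaptic gene lists did not pass. Medians were -0.0018 for 33 glutamatergic synapse genes (adjusted p = 0.903), 0.0056 for 28 genes of presynaptic vesicle release (0.903), -0.03 for 20 GABAergic synapse genes (0.294) and 0.03 for interneuron markers (0.752), all camera adjusted p-values with the preset correlation, as are those that follow. CA1 pyramidal cell markers had -0.02 (0.469) and those of CA2 and CA3 -0.04 (0.331), and immediate early genes, which follow neuronal activity, had 0.06 (0.0769). The score of glutamatergic synapse genes was 7.01 ± 0.0154 in vehicle and 7.02 ± 0.0414 in Visudyne samples. Grin2b, an NMDA receptor subunit, measured 966 ± 109 and 998 ± 59.3 CPM, Snap25, a vesicle fusion protein, 1525 ± 103 and 1440 ± 139, and Bdnf, a neurotrophin, 46.3 ± 2.60 and 42.7 ± 3.15. The activity-regulated genes Fos (5.94 ± 2.76 and 7.03 ± 1.05 CPM) and Arc (77.4 ± 24.4 and 85.7 ± 18.8 CPM) varied more between samples than between groups. Each of these 5 genes had an edgeR adjusted p of 0.9999.

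Apart from the reactive astrocyte, lymphatic endothelium and fibroblast lists, lists of glial and vascular cells did not pass either. Medians were 0.03 for 22 microglia genes (adjusted p = 0.205), 0.04 for disease-associated microglia (0.0637), where Lyz2 (0.65, SE 0.14) passed when adjusted over the list alone, and 0.04 for astrocytes (0.0768). They were 0.02 for the perivascular water channel complex (0.122), -0.01 for myelinating oligodendrocytes (0.867), 0.02 for oligodendrocyte precursors (0.867), 0.01 for brain endothelium and barrier (0.983) and -0.09 for mural cells (0.226). In the mural list Anpep had 0.64 (SE 0.20), while the smooth muscle genes Myh11 (-0.53, SE 0.25) and Tagln (-0.30, SE 0.21) were negative. Aqp4, the astrocytic water channel, measured 133.8 ± 16.1 CPM in vehicle and 138.9 ± 15.9 CPM in Visudyne samples, Gfap 226 ± 25.7 and 244 ± 19.1, Aif1 2.47 ± 0.361 and 2.59 ± 0.135, Cx3cr1 36.8 ± 3.62 and 37.0 ± 3.40, and Trem2 7.72 ± 0.673 and 7.70 ± 0.354. The myelin gene Mbp measured 486 ± 62.0 and 487 ± 53.4 CPM, and the tight junction gene Cldn5 11.9 ± 3.63 and 12.3 ± 3.48. Each of these 7 genes had an edgeR adjusted p of 0.9999.

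Genes linked to Alzheimer disease had a median of 0.01 (adjusted p = 0.897). App, the amyloid precursor, measured 854.9 ± 30.2 and 858.6 ± 58.9 CPM, and Apoe 724 ± 93.9 and 754 ± 63.9 CPM, each with an edgeR adjusted p of 0.9999. Other response lists did not pass: interferon response 0.07 (0.122), glucocorticoid response 0.0009 (0.983), heat shock and unfolded protein response 0.0007 (0.897), hypoxia and oxidative stress -0.0025 (0.897), circadian clock 0.01 (0.903) and cholesterol synthesis -0.0017 (0.867). Nuclear oxidative phosphorylation had -0.03 (0.0769), cytosolic ribosomal proteins -0.03 (0.173), proliferation 0.05 (0.897) and adult neurogenesis 0.02 (0.752). T, B and natural killer lymphocyte genes, of which 8 of 25 were tested, had 0.05 (0.268).

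Apart from the meningeal fibroblast list, markers of tissue next to the hippocampus did not pass. Medians were -0.11 for choroid plexus epithelium (adjusted p = 0.867), 0.18 for ependyma and motile cilia (0.230), 0.22 for blood (0.897), 0.01 for neocortex (0.897), 0.03 for thalamus and habenula (0.522) and -0.02 for striatum and septum (0.897). Single samples weighed on 2 of these: the choroid plexus score was 2.33 in vehicle 7 (next vehicle sample 1.22). The ependyma score was 1.82 in Visudyne 12 (next Visudyne sample 0.696). The choroid plexus transcript Ttr measured 43.7 ± 75.9 CPM in vehicle, where vehicle 7 alone had 179 CPM, and 15.4 ± 10.1 CPM in Visudyne samples. Other choroid members of smallest p were Kl (-0.23, SE 0.08), Lbp (0.47, SE 0.17) and Col8a1 (0.49, SE 0.25). The ependyma and cilia list members Rsph1 (0.32, SE 0.23), Ak7 (0.33, SE 0.33) and Rarres2 (0.82, SE 0.91), and the blood genes Fech (-0.09, SE 0.06), Alas2 (0.28, SE 0.36) and Hba-a1 (0.40, SE 0.52) had SEs of the order of their fold changes. Median, mean and test direction differed in sign for 9 lists that did not pass: blood and circadian clock (positive median, tested as down), GABAergic synapse, glutamatergic synapse, myelinating oligodendrocyte, hypoxia, striatum (negative median, positive mean), neocortex and glucocorticoid response (positive median, negative mean).

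**Figure D3:**
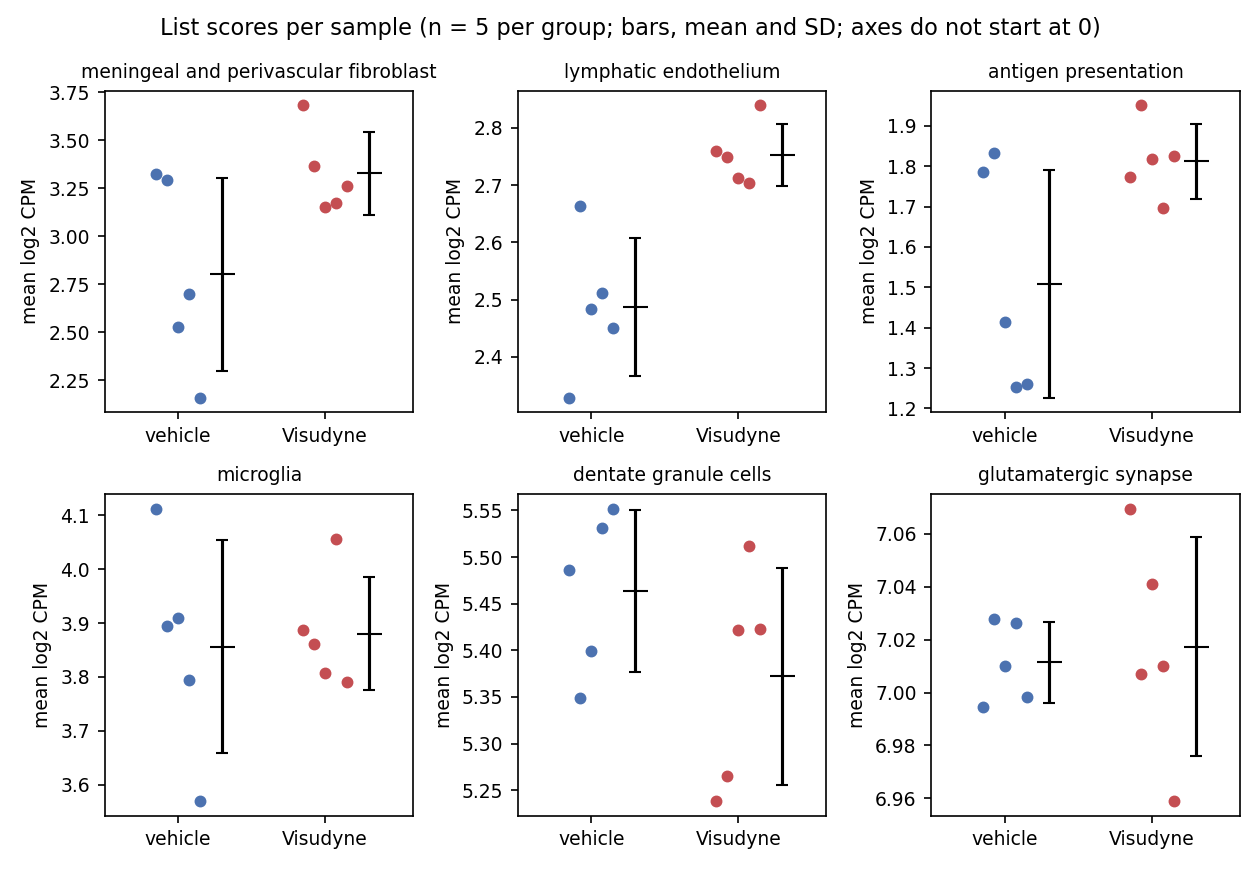
Mean log2 CPM of the members of 6 gene lists (vertical axes, not from 0) in each vehicle (blue) and Visudyne (red) sample, with the group mean and SD in black. All 5 Visudyne samples lie above all vehicle samples for lymphatic endothelium genes, and 2 of 5 do so for fibroblast genes.

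Library composition was compared between the groups over 10 measures, and none differed by the exact permutation test after adjustment (lowest adjusted p = 0.794). The small cytoplasmic 7SL RNA took 6.88 to 8.05% of the counts and the nuclear RNA Malat1 0.191 to 0.677%. The samples were spread along a first principal component that held 41.4% of the variance, from -53.8 in vehicle 1 to 53.1 in Visudyne 15, with group means of -3.94 ± 31.9 and 3.93 ± 36.7 (exact permutation p = 0.730, n = 5 each). Without these 2 samples, a choice made after the data were examined, 1 gene was higher and 1 lower, and 18 lists were higher and 1 lower.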

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

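The tests of outlying samples were set before the data were examined, and all tests of explanations in this part except the splits for the gene count were chosen after the results were seen. In 228 groups of 5 samples, of named genes, list scores and library measures, 19 samples stood apart from the other 4 by a gap of more than 0.71 of the group's range. Chance gives about 1 in 20 groups, or 11.4, if values are normally distributed. The groups overlap, since Ak7, Rsph1 and Rarres2 are part of the ependyma score and Fos and Arc of the immediate early gene score. Some of the 19 are therefore repeats of the same event, and their number is no test against 11.4.

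Visudyne 12 stood apart 8 times, with genes of the ependyma and motile cilia list prominent among them. It was highest in Ak7 (5.23 CPM, gap 0.844 of the range), Rsph1 (2.74 CPM, 0.765) and Rarres2 (2.38 CPM, 0.778), in the score of the ependyma list (1.82, next 0.696, gap 0.847), in Lbp (6.20 CPM, 0.831) and in Aqp4 (167 CPM, 0.756). It was lowest among Visudyne samples in Stab1 (12.9 CPM, 0.807) and Trem2 (7.09 CPM, 0.773).

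Vehicle 7 was highest in its group in Fat3 (45.3 CPM, next 1.88, gap 0.959), in the choroid plexus transcript Ttr (179 CPM, next 16.0, gap 0.934) and in Osmr (4.65 CPM, 0.731). Vehicle 13 was highest in the activity-regulated genes Fos (10.8 CPM, 0.828) and Arc (120 CPM, 0.791) and in the score of immediate early genes (4.18, next 3.91, gap 0.792). Vehicle 1 was highest in Apoe (887 CPM, 0.783) and in the astrocyte score (6.89, 0.743), and vehicle 10 lowest in the interferon response score (0.524, 0.810). Visudyne 6 was highest in the hemoglobin gene Hba-a1 (5.15 CPM, next 1.49, gap 0.821), and Visudyne 9 in Fbrs (3.56 CPM, 0.730).

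The samples were spread along a first principal component that the labels do not explain. The tables argue against the treatment as its source, since 1.61% of its variance lay between the groups and both groups had samples on both sides. A share of nuclear RNA that differs between the libraries is a candidate explanation that stays open: 6 long nuclear noncoding RNAs had a median correlation of 0.960 with the component, and the score of ribosomal protein genes had -0.950. For Malat1 Pearson's r was 0.990 and Spearman's rho 0.976 over 10 samples (permutation p = 1e-05 each, the smallest the permutations can give, adjusted 2e-05 over 2 relations), and r was 0.976 without the 2 samples farthest from the median. The component was computed from values that include Malat1, so these p-values do not test the explanation. The abundant nuclear RNA 7SK did not follow the component (r = -0.180 for log2 CPM and 0.298 for its share of the counts), so that a general difference in nuclear RNA is not established.

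Of 100 splits of the 10 samples into 5 and 5, the real one included, 2 gave at least the 4 genes of the real split, a share under 0.05. Such a count was uncommon, but this does not exclude chance, since a split that mixed the groups gave far more genes. The highest other split gave 453 genes. It set Visudyne 3, Visudyne 9, Visudyne 12, vehicle 1 and vehicle 10 against the rest, so this count points to a structure of the samples. Its source was not found: 4 of these 5 samples were the lowest along the first component, but 3 other splits that kept these 4 together gave 0, 0 and 1 gene. For gene lists with the preset correlation, 80 of the 100 splits gave at least the 8 lists of the real split, and the highest other split gave 23, so that chance cannot be excluded for the number of lists.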

How the results depend on the processing

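The omission of 2 samples was the only alternative chosen after the data were examined. No paired analysis was run, because the groups share no replicate numbers and no label joins a Visudyne to a vehicle sample. The numbers alternate between the groups (vehicle 1, Visudyne 3, vehicle 4 and so on), but pairing neighbours would be an assumption. Against 4 higher and 0 lower genes and 6 higher and 2 lower lists, higher genes numbered 2 with upper-quartile factors, 2 with mitochondrial genes removed, 13 with voom and sample quality weights, 0 with a minimum fold of 1.2, 19 with the sample number as covariate and 7 with 1 surrogate variable. DESeq2 gave 16 higher and 2 lower genes. The sample number gave 12 higher lists and 1 lower, the surrogate variable 11 higher, and removal of mitochondrial genes 1 lower, since that list could not be tested. Estimated correlation and fry each gave 0 lists in both directions. Leaving out each sample in turn gave 0 to 4 higher and 0 to 1 lower genes, and 3 to 11 higher and 1 to 6 lower lists. Higher lists numbered 11 without Visudyne 15 or vehicle 1 and 3 without vehicle 13; lower lists numbered 6 without Visudyne 3, 5 without Visudyne 12, 1 without Visudyne 15 and 4 without vehicle 4 or vehicle 7. Without vehicle 1 and Visudyne 15 together there were 1 higher and 1 lower gene, and 18 higher lists and 1 lower. The cause of these differences was not tested. Col12a1 kept its call in 18 of 22 alternatives (adjusted p up to 0.0871), Slc26a2 in 12, and Col6a2 and Col1a1 in 9 each, with adjusted p up to 0.940, 0.249 and 0.279. With the sample number as covariate the medians of called lists rose to 0.49 for fibroblasts, 0.14 for reactive astrocytes, 0.12 for antigen presentation and 0.15 for cytokines, and without both samples to 0.46, 0.19, 0.10 and 0.17. No called gene or list changed direction in any alternative. Fibroblast and dentate granule cell lists kept their calls in 18 of 20 alternatives, all except the estimated correlation and fry. Of 1421 values of named genes under alternatives 1363 stayed on their side of the threshold, 40 fell below it and 18 passed it, and of 818 values of lists 715, 37 and 66 did. Depth limits genes of a few counts, and in the simulation, whose genes varied independently of each other, 3.51% of 114 calls were false.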

Other observations

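Except for the lists and genes fixed in advance, the genes and tests of this part were chosen after the results were seen. Several transcripts that fell outside the rule for named genes also parted the groups, and none of them passed the main test. Over all genes tested, 61 parted the groups in this direction, against 76 expected by chance. The imprinted noncoding RNA H19, abundant in fetal tissue, measured 0.169 ± 0.0751 CPM in vehicle and 0.910 ± 0.345 CPM in Visudyne samples (log2 fold change 2.42, edgeR adjusted p = 0.0659, n = 5 each). Lox, the enzyme that crosslinks collagen, measured 0.421 ± 0.176 and 1.26 ± 0.274 CPM (1.58, edgeR adjusted p = 0.332), and the cytochrome Cyp2f2 0.0747 ± 0.0475 and 0.400 ± 0.0966 CPM (2.38, edgeR adjusted p = 0.137). Mrc2, a receptor for collagen uptake, measured 5.77 ± 1.47 and 9.26 ± 1.26 CPM (0.68, edgeR adjusted p = 0.992), and Slc26a7, an anion transporter related to Slc26a2, 1.07 ± 0.647 and 3.07 ± 0.651 CPM (1.51, edgeR adjusted p = 0.861). In each of these 5 genes all 5 Visudyne samples lay above all vehicle samples. DESeq2 called all 5, together with Col3a1, Fn1, Mgp, Adamtsl3, Lyz2, Kcnk5 and Car13, beside the 4 genes that edgeR called.

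The first pattern is the rise of Col12a1, Slc26a2, Col6a2 and Col1a1. More tissue left on the hippocampus at dissection was examined first for tissue that 5 solute carriers of meningeal fibroblasts follow (Slc6a13, Slc6a20a, Slc13a4, Slc22a6 and Slc47a1). Their summed CPM differed between the groups by 7.47 (SE 8.94, exact permutation p = 0.421). After this sum was regressed out, 4 of the 4 genes kept an exact permutation p of 0.0079, the value they had before. Col1a1 still differed by 9.14 CPM (SE 1.596) against 10.6 (SE 1.51) before. The 4 genes had been picked for their difference, and a sum that does not part the groups leaves it largely in place. Keeping it therefore does not exclude such tissue, and shows only that these carriers did not part the groups as the 4 genes did. After the mean log2 CPM of the carriers was regressed out of log2 CPM, 4 of the 4 genes kept an exact permutation p of at most 0.0238. Col1a1 then differed by 0.69 (SE 0.18) against 1.21 before. The carrier score includes Slc47a1, which itself parts the groups. Without it 4 of the 4 kept an exact permutation p of 0.0079, and Col1a1 differed by 1.05 (SE 0.15), Col6a2 by 0.75 against 0.85 before, Col12a1 by 0.72 against 0.77 and Slc26a2 by 0.43 against 0.45. Arachnoid barrier tissue, another part of the meninges, stays open as well. The markers Cdh1, Dpp4, Slc47a1, Crabp2, Krt8 and Krt18 summed to 6.62 ± 2.52 CPM in vehicle and to 5.39 CPM more in Visudyne samples, and with this sum regressed out 0 of the 4 genes kept an exact p under 0.05. That sum itself parted the groups completely, through Slc47a1, whose separation had been seen before, so tissue carried over and a response of arachnoid cells cannot be told apart. Without Slc47a1 the other 5 markers, of low counts, summed to 5.43 ± 1.66 and 7.78 ± 1.99 CPM (exact permutation p = 0.0873). With this sum regressed out 4 of the 4 genes kept an exact p of at most 0.0476, so the outcome differs with and without that marker. The differences still shrank with these 5 markers: Col1a1 to 6.17 CPM from 10.6, Col6a2 to 2.21 from 4.18, Col12a1 to 4.24 from 7.14 and Slc26a2 to 2.90 from 4.54. Of these 5, Cdh1 was 2.38-fold higher (SE 0.39 on the log2 scale), and log2 fold changes were for Dpp4 0.29 (SE 0.19), Crabp2 0.29 (SE 0.39), Krt8 0.14 (SE 0.41) and Krt18 -0.10 (SE 0.50), each with an edgeR adjusted p of 0.9999. A change of matrix genes beyond other fibroblast genes was not decided either. The score of 11 matrix genes minus that of the 5 solute carriers differed by 0.0514 on the log2 scale (exact permutation p = 0.770), since the carriers averaged 0.605 higher (exact permutation p = 0.127), mostly through Slc47a1. The other 4 carriers averaged 0.232 higher (exact permutation p = 0.524), and the matrix genes exceeded these by 0.424 (exact permutation p = 0.0794).

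The second pattern is the higher level of the class II genes Cd74, H2-Aa, H2-Ab1 and H2-Eb1, whose mean log2 CPM was -0.474 ± 1.04 in vehicle and 1.003 ± 0.259 in Visudyne samples (n = 5 each). These genes were picked because they were higher, so this difference is not tested. More microglia are argued against, since the score of the microglia list differed by 0.0246 (SE 0.100), and that of the class II genes by 1.48 (SE 0.481). Arrival with meningeal tissue, which holds border macrophages, stays open. With group means removed, the class II score followed the solute carriers with r = 0.900 (permutation p = 0.0080) and rho = 0.891 (permutation p = 0.0087). Each p is also the adjusted value over 2 relations, and r was 0.801 without the 2 farthest samples. This relation within groups does not by itself account for the difference between them. The 4 carriers other than Slc47a1 averaged 0.232 higher with Visudyne (exact permutation p = 0.524). Slc22a6 measured 7.72 CPM in vehicle 1 and 8.66 in vehicle 4, within the Visudyne range of 3.84 to 9.36. Cd74 measured 3.10 and 2.24 CPM in these vehicle samples, below the lowest Visudyne sample (3.35). After the carriers were regressed out, a difference of 0.557 remained (exact permutation p = 0.0714) of 1.48 before. The carriers include Slc47a1, which itself parts the groups, so part of this drop was fixed beforehand. The drop without Slc47a1 was not tested. A treatment effect on border macrophages beyond their number stays untested.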
